A study of Homo sapiens with 9 samples.

How the data were processed

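H3K9me3, a histone mark of constitutive heterochromatin, was profiled by Cut&Run in hTERT RPE-1, an established human retinal pigment epithelial line immortalised with telomerase. Cut&Run releases the DNA around an antibody-bound mark with a tethered nuclease, and the released fragments are sequenced. Per the labels' protocols, the cells stably overexpressed either mCherry or an mCherry fusion of lamin B1 (LmnB1), and doxycycline was given at 0.05 ug/mL for 24 hours. DNA was isolated with an EpiCypher CUTANA kit and the antibody ab8898, and libraries were made with NEBNext Ultra II, per the labels' protocols. Of the 9 samples in the series, 8 are H3K9me3 libraries, from 2 clones per construct (LmnB1_16 and LmnB1_6, mCherry_3 and mCherry_4) with 2 biological replicates per clone. The 1 input sample, from wild-type cells, is not used here on its own.

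Each of the 8 libraries has 1 deposited list of enriched domains, called per library without pooling replicates, and the lists hold 60138 domains on chromosomes 1 to 22, X and Y. The submitters' processing notes name SICER, DiffBind 3.0.15, DESeq2, deepTools and the builds GRCh38 and hg38, without saying which step each served. The aligner is not given in the sources used here. For each domain the deposited lists give the count of H3K9me3 reads and the count of input reads. They also give, as the authors' values, a p-value, a second p-value adjusted for false discovery, and the log2 enrichment over input. The deposited score is 100 times that log2 value. In every list the lowest log2 value lay just above 0.6, so a domain is listed only past that enrichment, and all starts fell on steps of 1000 bp. The log2 value equalled the log2 ratio of both counts plus 1 constant per list, and that constant gave the depth of each library relative to input. Input counts were identical in 2546 of 2546 domains listed with the same coordinates in several libraries, so all lists share 1 control. Counts exist only for domains in a library's own list, so no count matrix over common regions could be made, and count models were not run on them. A region outside a list is not shown to lack reads, since it may lie just below the authors' threshold. The scores were used to rank domains within a list. The log2 values also served to describe the enrichment of each library and to compare the replicates of LmnB1_6.

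Domains were compared by the bases they cover. Gene positions came from a table of 20037 protein-coding genes on the GRCh38 assembly, which holds starts and ends but no strand, exons or introns. The domain lists name the same build in the processing notes. For each library, the covered percent was computed for 500 kb bins, for gene bodies and for chromosomes (in Mb, because no chromosome lengths were at hand). Bins and genes with a mean covered percent of at least 5 over the 8 libraries were tested with limma 3.58.1 in R 4.3.3, with the clone as a random block and Benjamini-Hochberg adjustment at 0.05. A difference is given in percentage points, LmnB1 minus mCherry. Values per library, gene lists and chromosomes were compared with an exact two-sided permutation test over the 70 assignments of the libraries, whose smallest p is 0.0286. These p-values treat 2 replicates of a clone as independent, and over the 6 assignments of whole clones the smallest p is 0.333. Of the 25 gene lists, 15 would need the smallest p before any could pass the adjustment, and 14 of the 24 chromosomes would. Overlap between libraries is the Jaccard index, the shared bases divided by the bases covered in either. Regions of the merged lists were called construct-specific when at least 50% covered in all 4 libraries of one construct and at most 10% in all 4 of the other. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

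The functions were tested on simulated data. For limma, known shifts were planted in 200 bins and 200 genes of simulated libraries. Of the planted bins, 8% were recovered at a shift of 20 points, 32% at 40, 46% at 60 and 70% at 80. Of the planted genes, 16% were recovered at 20 points, 34% at 40, 32% at 60 and 58% at 80. The unchanged features kept the measured pairs of replicates, shuffled between clones, so they still varied from clone to clone. False calls made up 13.3% of all calls for bins (12 of 1943 unchanged bins) and 21.1% for genes (19 of 2104 unchanged genes), above the nominal 5%, so limma's adjusted p-values are too small for data with this variation between clones. These percents rest on the planted shifts, which supplied 78 true calls for bins and 71 for genes, and do not carry over to the measured data. There 5 bins and 7 genes were called, fewer than the 12 and 19 false calls here. The share of false calls among those 5 bins and 7 genes is not known. Planted values were not held within 0 and 100%.

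Replicates were compared through the counts of domains listed with identical coordinates. In the mCherry_3 pair a difference beyond sampling noise was not detected (chi-square 246 on 228 degrees of freedom over 229 domains, p = 0.197). It was detected in the LmnB1_16 pair, at a similar ratio over more domains (chi-square 712 on 647 degrees of freedom, p = 0.038), in LmnB1_6 (p = 0.000368) and in mCherry_4 (p = 0.0162). Between clones, it was not detected for LmnB1_6 replicate 2 with mCherry_3 replicate 2 (chi-square 58.5 on 46 degrees of freedom over 47 domains, p = 0.102). An undetected difference is thus not particular to replicates of 1 clone. The domain lists of the mCherry_3 pair were not copies of each other, since 1290 of 6115 domains of replicate 1 had 0 bp covered in replicate 2. Both were kept as libraries of their own, and values without either member are given beside the counts of specific domains, genes, lists and chromosomes.

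Before the data were examined, 25 gene lists, the tests, the naming rule and most alternatives were fixed. The lists were zinc finger genes, zinc finger genes on chromosome 19, clustered protocadherins, olfactory receptors, taste and vomeronasal receptors, keratin-associated proteins, keratins, beta-defensins, HOX genes, replication-dependent histones, cancer-testis antigens, UDP-glucuronosyltransferases, type I interferons, HLA genes, ribosomal proteins, nuclear envelope proteins, H3K9 methylation and HP1 machinery, retinal pigment epithelium markers, epithelial junction genes, mesenchymal and matrix genes, long neuronal genes, cell cycle genes, senescence-associated secreted factors, imprinted genes, and globin and serum albumin family genes. Named genes were up to 12 per direction past the adjusted threshold with groups fully apart, none within 1 Mb of another. Up to 6 that did not pass were added where fewer than 12 did, with 2 members of each list with the highest mean and 2 with the largest difference, and LMNB1, LMNB2, LMNA and LBR. Named regions were the 5 bins per direction with the smallest p, the 5 longest construct-specific domains and the 5 longest domains present in all 8 libraries. Alternatives were each library left out in turn, the highest-scoring 50% of each list, domains of at least 10 kb, equal covered length, autosomes alone, domains under 10 kb apart joined, a replicate block, clone means, no clone block, an arcsine square root, values minus the library mean, no filter, bins of 100 kb and 1 Mb, and other definitions of shared and specific domains. For equal covered length, the highest-scoring domains of each list were kept up to the length of the shortest list, mCherry_4 replicate 2 (320 Mb). That list kept its weakest domains while longer lists lost theirs. Libraries were then compared at unlike enrichment, so this is no neutral correction for length. A planned comparison around gene starts was not run because the gene table has no strand. Both gene ends with 5 kb on either side were used in its place, chosen after seeing the data. So was leaving out a pair of doubted libraries, LmnB1_6 replicate 2 and mCherry_4 replicate 1, the latter with the lowest depth. LmnB1_6 has the lowest overlap between replicates (0.529), and its replicate 2 the lowest pooled log2 enrichment (0.71). mCherry_4 replicate 2, with the shortest covered length (320 Mb) and a pooled log2 of 0.722, was kept, so weak libraries were not left out evenly from both constructs. Leaving out each library in turn, or the doubted pair, from the chromosomes' shares of covered length was also chosen after seeing the data. No values of chromosome Y are given.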

Results

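H3K9me3 domains were compared between hTERT RPE-1 cells overexpressing lamin B1 fused to mCherry and cells overexpressing mCherry alone, to ask whether an excess of this nuclear lamina protein moves heterochromatin. Lamin B1 is a filament protein at the inner face of the nuclear envelope, where much of the H3K9me3-marked chromatin lies. The LmnB1 group held 4 libraries, replicates 1 and 2 of the clones LmnB1_16 and LmnB1_6, and the mCherry group held 4, replicates 1 and 2 of mCherry_3 and mCherry_4. H3K9me3 reads inside domains numbered 10321442 and 9029907 in LmnB1_16 replicates 1 and 2, and 10144777 and 4467294 in LmnB1_6. They numbered 6959349 and 6869411 in mCherry_3, and 2855378 and 3840496 in mCherry_4. Counts of the mCherry_3 pair over domains with identical coordinates did not differ detectably beyond sampling noise, while their lists differed, so values without either member stand beside the counts of specific domains, genes, lists and chromosomes. Depth relative to the shared input ran from 0.880 to 1.01 in the LmnB1 libraries. In the mCherry libraries it ran from 0.421 (mCherry_4 replicate 1) to 0.859. Every LmnB1 library was thus deeper than every mCherry library, so depth cannot be told apart from the construct. Pooled over all domains of a library, the authors' log2 enrichment over input ran from 0.71 in LmnB1_6 replicate 2 to 1.14 in LmnB1_16 replicate 1.

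H3K9me3 domains covered 610 and 534 Mb in LmnB1_16 and 646 and 357 Mb in LmnB1_6. They covered 529 and 528 Mb in mCherry_3 and 429 and 320 Mb in mCherry_4. The mean was 537 ± 129 Mb with LmnB1 and 451 ± 99.4 Mb with mCherry (SD, n = 4 each), a difference of 85.4 Mb that was smaller than the spread between libraries (exact permutation test, two-sided p = 0.257). LmnB1 libraries held 8114 ± 2523 domains and mCherry libraries 6921 ± 1175 (exact permutation p = 0.457), with a mean of median lengths of 17.3 ± 13.3 kb and 23.8 ± 7.41 kb (exact permutation p = 0.429). Over these 3 values the adjusted p was 0.457 for each. The difference in covered length was 41.5 Mb without mCherry_4 replicate 2, 48.9 Mb without LmnB1_6 replicate 1 and 145.5 Mb without LmnB1_6 replicate 2. That in domain number was 124 without LmnB1_16 replicate 1 and 2110 without LmnB1_6 replicate 2, and that in median length -13.1 kb without LmnB1_6 replicate 2, -3.42 kb without LmnB1_16 replicate 1 and -3.75 kb without mCherry_4 replicate 1. Domains longer than 1 Mb numbered 120 and 82 in LmnB1_16, 71 and 3 in LmnB1_6, 51 and 49 in mCherry_3, and 4 and 1 in mCherry_4, so replicates of LmnB1_6 differed more from each other than the constructs did. The direction of the difference in domain number turned when only domains of at least 10 kb were counted (a mean difference, LmnB1 minus mCherry, of -1111, exact permutation p = 0.314), and at equal covered length (-61.5, exact permutation p = 0.943).

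**Figure D1:**
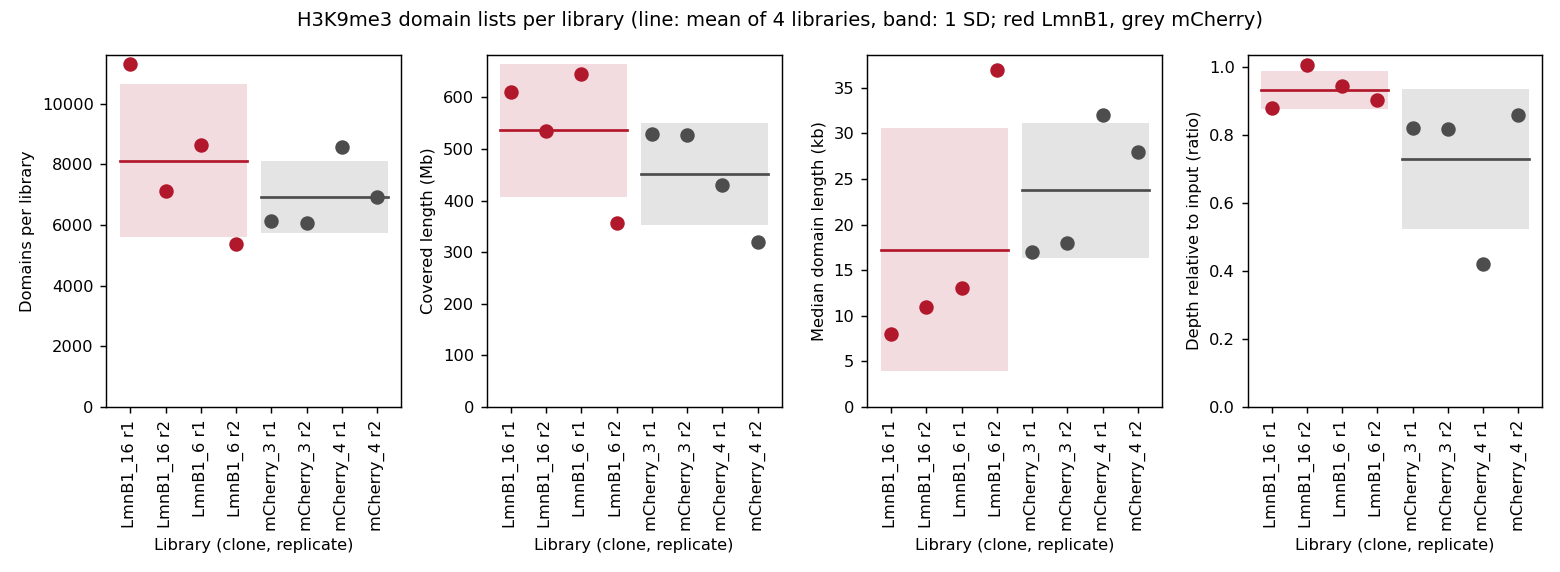
Number of H3K9me3 domains, covered length (Mb), median domain length (kb) and depth relative to input (ratio) of each of the 8 libraries, with points for libraries, lines for the mean of 4 and bands for 1 SD. Covered length ran from 320 to 646 Mb, the bands of both constructs overlap in every panel, and mCherry_4 replicate 1 sits at a depth ratio of 0.421. In depth every LmnB1 library lies above every mCherry library.

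Some large heterochromatin blocks carried H3K9me3 in all 8 libraries. Of 827 Mb covered in any library, 168 Mb (20.3%) was covered in all 8 and 140 Mb in 1 library. The longest merged domain present in all 8 libraries spanned chromosome 21 from 18876001 to 25313000 and held NCAM2, a neural cell adhesion gene, with 91.3 ± 12.7% covered with LmnB1 and 85.7 ± 13.7% with mCherry (SD, n = 4). The next ones were on chromosome 11 from 38824001 to 43251000 around the synaptic adhesion gene LRRC4C, chromosome 8 from 135882001 to 140010000 over FAM135B, COL22A1, KCNK9 and TRAPPC9, chromosome 13 from 53098001 to 57140000, and chromosome 8 from 2484001 to 6112000 around CSMD1. Their mean covered percent was 85.1, 95.5, 96.5 and 89.6 with LmnB1 and 80.6, 85.3, 94.2 and 87.9 with mCherry. In all, 157 protein-coding genes were covered over more than 90% of their length in all 8 libraries, and 15897 of 20037 were at 0 in all 8.

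Libraries of one construct did not share more domain sequence than libraries of different constructs. The Jaccard index of covered bases averaged 0.576 ± 0.105 over 8 pairs of the same construct and different clones, and 0.578 ± 0.132 over 16 pairs of different constructs. Replicates of 1 clone averaged 0.693 ± 0.162 over 4 pairs, with 0.844 in mCherry_3 and 0.529 in LmnB1_6. The difference between same and different construct was -0.00248, and 21 of 35 splits of the libraries gave one as large (exact p = 0.6, one-sided). Its sign turned in several alternative settings, none of which gave a p below the 0.0857 found when domains were counted in place of bases, by an exact test over splits.

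**Figure D2:**
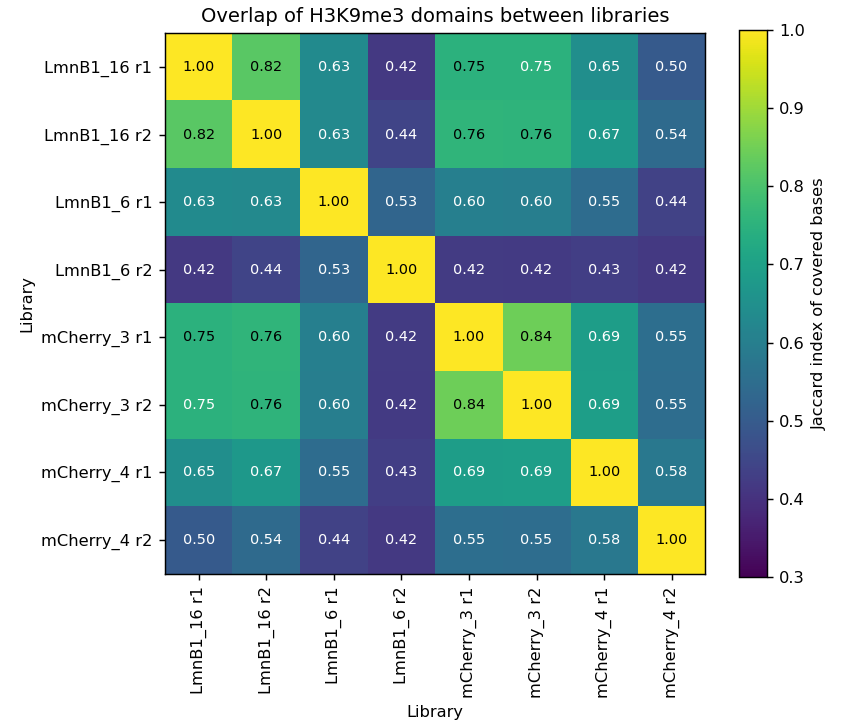
Jaccard index of covered bases, from 0.3 to 1 on the colour scale, for each pair of the 8 libraries. The mCherry_3 pair overlaps most (0.844), and LmnB1_6 replicate 2 has an index of 0.529 with its own clone and from 0.415 to 0.443 with the other clones.

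Among 12058 merged regions, 25 were listed as covered by H3K9me3 domains with LmnB1 and not with mCherry, and 0 showed the reverse. The longest lay on chromosome 5 from 100342001 to 100492000 (150 kb), with 80.7 ± 15.3% covered with LmnB1 and 0 with mCherry (SD, n = 4), and overlapped no protein-coding gene. The others among the longest were on chromosome 3 from 25989001 to 26033000 and from 41117001 to 41139000, on chromosome 5 from 56383001 to 56401000, and, at 16 kb each, on chromosome 5 from 37791001 to 37807000 and on chromosome 14 from 70861001 to 70877000. The 25 regions spanned 0.476 Mb with a median of 13 kb, and 6 overlapped a protein-coding gene, CEP112, KIF15, PALLD, EPB41L2, SYN2 or TENM3 (these 6 were named after their values were seen). EPB41L2 encodes a membrane skeleton protein and KIF15 a mitotic kinesin. In comparison, 292 merged regions were covered over at least 50% in all 8 libraries. The LmnB1 count was 622 without LmnB1_6 replicate 2 and 41 without either mCherry_3 replicate, and the mCherry count was 4 without mCherry_4 replicate 2, 2 without LmnB1_6 replicate 1 and 1 without either LmnB1_16 replicate or without mCherry_3 replicate 2. At equal covered length there were 21 LmnB1 regions and 3 mCherry regions. The counts rested on the definition, with 2 and 0 at 80% or more in all 4 and 0 in the others, and 966 and 17 in at least 3 of 4 against at most 1 of 4. Of 35 splits of the libraries, 5 gave at least 25 regions.

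In 500 kb bins, H3K9me3 coverage was higher with LmnB1 in 5 of 2143 bins and lower in 0 (limma, adjusted p below 0.05), and 3 of the 5 formed 1 block on chromosome 14 from 83500001 to 85000000. There the covered percent with LmnB1 was 91.2 ± 6.6, 96.2 ± 3.5 and 97.0 ± 3.65 in the successive bins, against 12.7 ± 7.66, 7.8 ± 7.6 and 8.85 ± 6.05 with mCherry (SD, n = 4), and LOC124903401 was the one protein-coding gene in the block. The bin on chromosome 8 from 87000001 to 87500000, which holds part of the cyclic nucleotide-binding domain gene CNBD1, was 95.6 ± 3.7% covered with LmnB1 and 9.4 ± 4.28% with mCherry (86.2 points, SE 5.49, limma adjusted p = 0.000476). The bin on chromosome 6 from 120500001 to 121000000, with no protein-coding gene, was 84.9 ± 11.1% covered with LmnB1 and 10.3 ± 3.36% with mCherry (limma adjusted p = 0.0141). In these 5 bins LmnB1_6 replicate 2, which covered less of the genome than either mCherry_3 library, had at least 82.8% covered, while mCherry_3 had at most 15.0%. The bins were picked by the test for high values with LmnB1 and low values with mCherry, so this order is no separate evidence. At an unadjusted p below 0.05 there were 78 bins, 65 of them higher with LmnB1, while minus the library mean 63 of 119 were higher. The 78 are fewer than the share of 0.05 that chance alone would give among 2143 bins, and the 119 slightly more. At equal covered length 0 bins were higher and 1 lower in limma (69 unadjusted, 23 of them higher), and in the highest-scoring 50% of each list 0 passed in limma (62 unadjusted, 21 of them higher). The differences of the bins on chromosome 8, on chromosome 14 from 84500001 and on chromosome 6 shrank to 20.8, 52.8 and 40.6 points at equal covered length and to 18.3, 25.3 and 32.65 points in the highest-scoring 50%. The shortest list was not cut at equal covered length, so libraries were compared at unlike enrichment there. With 1 library left out, the unadjusted count ran from 37 (without LmnB1_6 replicate 1) to 108 (without LmnB1_16 replicate 2). Without LmnB1_6 replicate 1, 3 of the 5 bins remained among 3 called, 3 remained without LmnB1_6 replicate 2 and 4 without mCherry_4 replicate 1, the bin on chromosome 6 not passing each time at differences of 70.2, 78.3 and 75.5 points, close to the 74.6 with all libraries (limma adjusted p of 0.212, 0.0591 and 0.0785), and 8 bins were called without LmnB1_16 replicate 2.

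Bins next in order did not pass with all libraries. On chromosome 11 from 98500001 to 99000000 coverage was 81.9 ± 15.5% with LmnB1 and 4.1 ± 5.66% with mCherry, and on chromosome 12 from 71000001 to 71500000, over TSPAN8 and LGR5, it was 63.6 ± 10.4% and 6.35 ± 6.6% (SD, n = 4, limma adjusted p = 0.0565 for both). Both passed without LmnB1_16 replicate 2 (limma adjusted p of 0.0185 and 0.0261), with domains under 10 kb apart joined, with a replicate block and without a clone block, and the first also minus the library mean. The lower values with LmnB1 that came closest were on chromosome 14 from 21500001 to 22000000, over METTL3, SALL2 and olfactory receptors such as OR10G3 (7.8 ± 5.83% and 50.8 ± 16.9%, limma adjusted p = 0.683, and 0.0311 minus the library mean), and on chromosome 11 from 113000001 to 113500000, over NCAM1 and DRD2 (1.4 ± 2.8% and 21.8 ± 5.01%, limma adjusted p = 0.737). The remaining ones were on chromosome 1 from 177500001 to 178000000 at SEC16B (2.15% and 16.8%), chromosome 16 from 20000001 to 20500000 at UMOD and GP2 (6.95% and 55.8%) and chromosome 22 from 47000001 to 47500000 at TBC1D22A (3.25% and 32.7%), each at a limma adjusted p of 1.0.

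**Figure D3:**
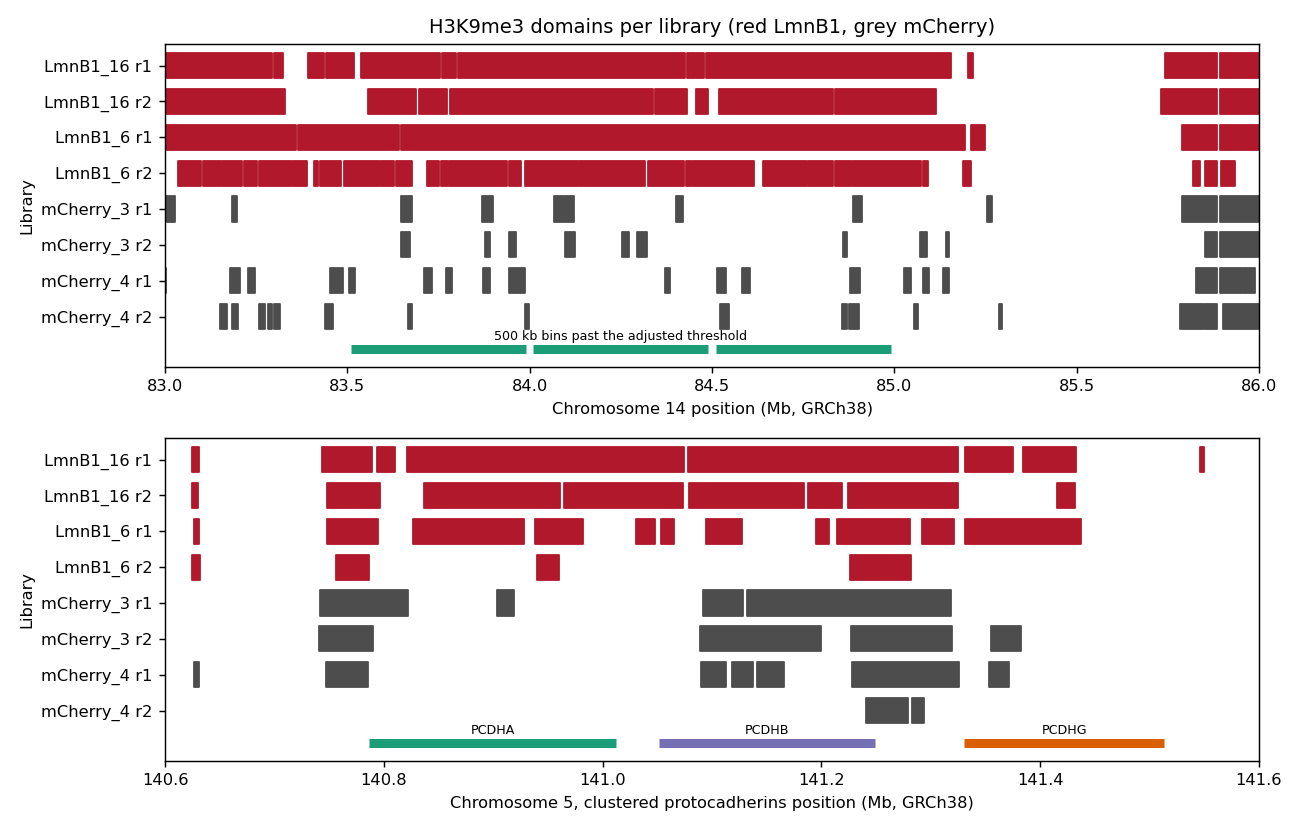
H3K9me3 domains (bars) in the 8 libraries along chromosome 14 around the 3 bins past the adjusted threshold (positions in Mb, GRCh38) and along the clustered protocadherins of chromosome 5, with PCDHA, PCDHB and PCDHG marked below. All 4 LmnB1 libraries cover at least 85.4% of each of the 3 bins and the mCherry libraries at most 22.8%, while the PCDHA genes are covered mainly in LmnB1_16 and in LmnB1_6 replicate 1.

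Among 2304 protein-coding genes tested, H3K9me3 coverage was higher with LmnB1 over 5 and lower over 2 (limma, adjusted p below 0.05). FOXA2 (chromosome 20, 22580998 to 22585490), a forkhead factor of endodermal development, was covered over 100% of its length in all 4 LmnB1 libraries and 0 in all 4 mCherry libraries (SE 1.74 points, limma adjusted p = 2.99e-07). Its values did not vary within either group. That SE is borrowed from all genes tested, the same 1.74 as for ZNF135 at 100% in all 8 libraries, and is not a measured spread. The very small adjusted p-values of such genes, here and below, reflect saturated values. In the exact permutation test the smallest p is 0.0286 over libraries and 0.333 over whole clones. TSPAN8 (chromosome 12, 71125096 to 71157999), a tetraspanin, was 95.5 ± 8.97% covered against 0. HSPB8 (chromosome 12, 119178931 to 119194746), a small heat shock protein gene, was 95.2 ± 9.71% covered against 0 (limma adjusted p = 0.000916). CLVS2 (chromosome 6, 122996235 to 123072925) was 92.7 ± 8.29% covered against 0, and CNBD1 (chromosome 8, 86866415 to 87428652) 86.5 ± 9.67% against 9.43 ± 5.02% (SD, n = 4). For TSPAN8 and CLVS2 the limma adjusted p was 0.000805, and for CNBD1 it was 0.00153. Coverage was lower over SPRR2E (chromosome 1, 153093135 to 153094526), at 0 in all 4 LmnB1 libraries and 100% in all 4 mCherry libraries (limma adjusted p = 2.99e-07). SPRR2B nearby (chromosome 1, 153070226 to 153087799) was at 0 against 90.7 ± 12.9% (limma adjusted p = 0.00219). It lies outside the naming rule and was chosen after its values were seen. SPRR2 genes encode small proline-rich proteins of the cornified envelope and are close copies of one another, so reads from one copy can be assigned to another and their coverage is uncertain.

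The count of higher genes was 55 without LmnB1_6 replicate 2 (lower, 3) and 9 without either mCherry_3 replicate (lower, 2), and the count of lower genes was 8 without mCherry_4 replicate 2 and 4 without LmnB1_16 replicate 1. Without LmnB1_6 replicate 1, 6 of the 7 genes remained, all but SPRR2B. At equal covered length 7 genes were higher and 2 lower, and 1 of the 7 above, HSPB8, was among them, with FOXA2, TSPAN8, CLVS2, CNBD1 and SPRR2E at differences of 50, 50, 45.2, 23.9 and -50 points. In the highest-scoring 50% of each list 4 genes were higher and 1 lower, and HSPB8 was again the one of the 7 called. There TSPAN8, CLVS2 and CNBD1 differed by 50, 25 and 19.04 points, and FOXA2 and SPRR2E fell under the filter on coverage and were not tested. CLVS2 and CNBD1 did not pass around both gene ends, a setting chosen after seeing the data (82.5 and 67.2 points, limma adjusted p of 0.188 and 0.365), nor did CNBD1 minus the library mean (70.4 points, limma adjusted p = 0.0642). All 4 LmnB1 values lay above all 4 mCherry values in 62 tested genes and below in 9, where chance gives 1.43%, or 32.9 genes, in each direction if the 8 libraries were independent. That number takes neither the shared clones nor tied values into account. At an unadjusted p below 0.05 there were 99 genes, 84 of them higher with LmnB1, while minus the library mean 60 of 123 were higher and at equal covered length 40 of 60. The 99 are fewer than the share of 0.05 that chance alone would give among 2304 genes, and the 123 slightly more. With 1 library left out, the unadjusted count ran from 36 (without LmnB1_6 replicate 1) to 147 (without LmnB1_6 replicate 2).

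Several genes with groups fully apart did not pass with all libraries. The keratin gene KRT34 was covered over 100% in 3 LmnB1 libraries, 13.3% in LmnB1_6 replicate 2 and 0 with mCherry, and PCDHA8 was covered over 100%, 97.7%, 76.4% and 11.7% in the LmnB1 libraries and 2.34 ± 4.67% with mCherry (limma adjusted p = 0.902 for both). DPPA2, CRISPLD1, ADAMTSL3 and PLAAT1 had means of 100%, 100%, 86.1% and 59.2% with LmnB1 and 24.8%, 31.5%, 17.2% and 0 with mCherry (limma adjusted p from 0.77 to 0.902). For DPPA2 the mCherry mean came from 1 library, mCherry_3 replicate 2 at 99.1%, and DPPA2 passed at a difference of 100 points without it, at equal covered length and in the highest-scoring 50% of each list (limma adjusted p of 1.03e-06, 1.79e-07 and 1.32e-05). In the other direction OOSP4B had 11.0 ± 21.9% and 100% (limma adjusted p = 0.121), NCAM1, a neural cell adhesion gene, 7.22 ± 9.44% and 45.8 ± 7.76% (limma adjusted p = 0.243), and SLC9A4, ZNF860, ZNF41 and ZNF514 0, 45.6%, 16.1% and 55.1% with LmnB1 and 44.0%, 76.2%, 44.9% and 67.4% with mCherry (limma adjusted p from 0.887 to 0.902). CRISPLD1 and ZNF860 passed without mCherry_4 replicate 2 (limma adjusted p of 0.0262 and 0.00635), ADAMTSL3 and OOSP4B without LmnB1_16 replicate 2 (0.0279 and 6.82e-06), KRT34 and PCDHA8 without LmnB1_6 replicate 2 (2.16e-07 and 0.00467), and OOSP4B without a clone block (0.0218). Without LmnB1_6 replicate 2, 58 genes passed, the 7 above among them, and 19 were clustered protocadherins, adhesion genes of neurons. They included PCDHA1 through PCDHA13, for example PCDHA5 at 100%, 89.8% and 76.0% in the remaining LmnB1 libraries and at most 8.59% with mCherry (limma adjusted p = 0.00517). The annotated PCDHA genes overlap and share 1 end at 141012347 on chromosome 5, so they are not separate measurements. Olfactory receptors made up 6 of the 58 and zinc finger genes 4. Leaving out mCherry_4 replicate 1 as well, an alternative chosen after seeing the data, gave 54 higher and 4 lower, 14 of them protocadherins.

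Among gene families, zinc finger genes on chromosome 19 were covered most, over 59.7 ± 11.6% of the gene body with LmnB1 and 52.6 ± 11.2% with mCherry (246 genes, SD, n = 4, exact permutation p = 0.429). ZNF135 and ZNF177 were at 100% in all 8 libraries, while ZNF417 was at 100% in both LmnB1_16 libraries and 0 elsewhere and ZNF529 at 75.2 ± 30.9% and 28.7 ± 19.4%. All 510 zinc finger genes averaged 41.9 ± 8.12% and 37.8 ± 7.93%, with ZNF140 at 100% throughout. Clustered protocadherins (53 genes) averaged 45.8 ± 28.0% and 17.1 ± 13.0% (exact permutation p = 0.143, adjusted 0.595), with PCDHB15 at 100% in all 8 libraries, PCDHB2 at 75.0% in both groups and PCDHB1 at 69.9 ± 47.6% and 0. Long neuronal genes averaged 45.6 ± 11.3% and 38.4 ± 6.16%, including PCDH17 (97.8% and 95.5%), GRM7 (96.2% and 96.0%), CTNNA3 (66.4% and 19.9%) and NKAIN2 (44.3% and 0). Olfactory receptors averaged 34.8 ± 10.7% and 30.8 ± 5.06%, with OR10AG1 and OR10S1 at 100% throughout and OR2T3 and OR2T27 at 75.0 ± 50% and 0. Keratin-associated proteins averaged 38.6 ± 4.41% and 37.6 ± 5.54%, with KRTAP11-1 and KRTAP13-1 at 100% throughout, KRTAP4-6 at 75.0% and 0 and KRTAP2-2 at 50% and 0. Without LmnB1_6 replicate 2, PCDHB1 (limma adjusted p = 0.00155) and OR2T3, OR2T27 and KRTAP4-6 (limma adjusted p = 2.16e-07 each) passed.

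The lists with the smallest p were taste and vomeronasal receptors and retinal pigment epithelium markers. Taste and vomeronasal receptors averaged 13.0 ± 2.61% and 7.23 ± 1.44% (exact permutation p = 0.0286, the smallest possible, adjusted 0.357), higher in 4 of 4 LmnB1 libraries than in any mCherry library, with VN1R2 and VN1R4 at 100% in all 8, VN1R1 at 75.0% and 24.3% and the bitter receptor TAS2R16 at 100% in LmnB1_6 and 0 elsewhere. Retinal pigment epithelium markers averaged 2.92 ± 1.51% and 0 (exact permutation p = 0.0286, adjusted 0.357). The largest parts of that difference came from genes in different clones. MITF, a melanocyte and pigment epithelium factor, was covered over 100% and 64.4% in LmnB1_6, and OTX2, an eye and forebrain homeobox gene, over 100% and 29.3% in LmnB1_16. UDP-glucuronosyltransferases, which conjugate steroids and drugs, averaged 24.7 ± 21.4% and 0.435 ± 0.584% (exact permutation p = 0.0571, adjusted 0.476), at 50.7% and 31.7% in LmnB1_6 and 15.4% and 1.09% in LmnB1_16. UGT2B11 and UGT2B15 were at 100% in both LmnB1_6 libraries and 0 elsewhere. UGT2B genes, like many olfactory receptors, are close copies of one another, so reads could be assigned to the wrong copy and these values are uncertain. Relative to all genes of the library, the smallest p over all lists was 0.0571 in the exact permutation test.

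The remaining lists differed little between constructs. Imprinted genes averaged 17.9 ± 4.66% and 17.5 ± 5.42%, with NDN at 100% throughout, ZIM2 at 100% and 97.1%, MKRN3 at 25.0% and 71.6% and MAGEL2 at 75.0% and 41.8%. Beta-defensins averaged 11.4 ± 4.19% and 12.5 ± 2.65%, with DEFB112 at 100% throughout and DEFB113 and DEFB114 at 75.0% and 100%. Senescence-associated secreted factors averaged 9.48 ± 1.72% in both constructs, with the chemokine genes CCL2 and CCL7 at 100% in all 8 libraries and AREG at 0. Mesenchymal and matrix genes averaged 8.25 ± 1.98% and 6.36 ± 3.56%, with THBS2 at 97.4% and 72.4%, COL5A1 at 91.0% and 74.5% and COL11A1 at 31.5% and 0. Cancer-testis antigens averaged 4.88 ± 1.33% and 4.81 ± 2.08%, with MAGEB16 at 100% and 75.0%, SPANXN2 at 25.0% and 82.2% (limma adjusted p = 0.0352 without LmnB1_16 replicate 1) and SPANXN3 at 15.8% and 90.1%. Keratins averaged 3.32 ± 2.29% and 3.0 ± 2.02%, with KRT25 at 51.8% and 58.4% and KRT26 at 7.39% and 59.8%. HOX genes averaged 1.79 ± 2.1% and 0, led by HOXB8 and HOXD10, at 100% in 1 library each. HLA genes averaged 0 and 0.943 ± 1.77%, led by HLA-DPB1 at 70.7% in mCherry_3 replicate 2, with exact permutation p of 0.429 for both HOX and HLA genes.

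A further set of lists was almost free of H3K9me3 domains in both constructs, as were most of the 20037 genes. Ribosomal protein genes averaged 0.595 ± 0.687% with LmnB1 and 0 with mCherry, from the retrogene RPL10L in LmnB1_6, while RPL10 was at 0. Cell cycle genes averaged 0.0974 ± 0.0939% and 0, with CDK6 at 2.37% and RB1 at 2.11% with LmnB1. The H3K9 methylation and HP1 machinery averaged 0.302 ± 0.29% and 0.0209 ± 0.0417%, with ATF7IP, KDM4B and SETDB1 at 3.1%, 1.49% and 1.95% with LmnB1. Nuclear envelope proteins averaged 0.347 ± 0.406% and 0.0498 ± 0.0576%, led by LEMD3 at 5.71% and 0, with NET1 at 2.15% and 0 and SYNE2 at 0.968% and 1.35%. Epithelial junction genes averaged 0.0467 ± 0.0596% and 0.0571 ± 0.114%, with CLDN10 at 1.54% and 1.88% and CDH1 at 0. Replication-dependent histones (such as H1-1 and H1-2), type I interferons (IFNA1, IFNA10) and globin and serum albumin family genes (AFM, AFP) were at 0 in all 8 libraries. LMNB1 itself (chromosome 5, 126776623 to 126837020), LMNB2, LMNA and LBR were also at 0 in all 8. The mean over all 20037 genes was 5.76 ± 1.6% with LmnB1 and 4.85 ± 1.47% with mCherry. Subtracting that mean lowered the difference of every list by 0.916 points, so lists that differed by less, such as keratins and imprinted genes, turned negative by construction. Of the 25 lists, 0 passed the adjusted threshold in the exact permutation test, 2 reached an unadjusted p below 0.05, and adjusted over the list alone 0 members of any list passed in limma, as over all genes tested. The unadjusted count of lists was 0 without any 1 of the 4 mCherry libraries (smallest exact permutation p 0.0571), 1 without LmnB1_6 replicate 1, 6 without LmnB1_6 replicate 2 and 1 in the highest-scoring 50% of each list.

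**Figure D4:**
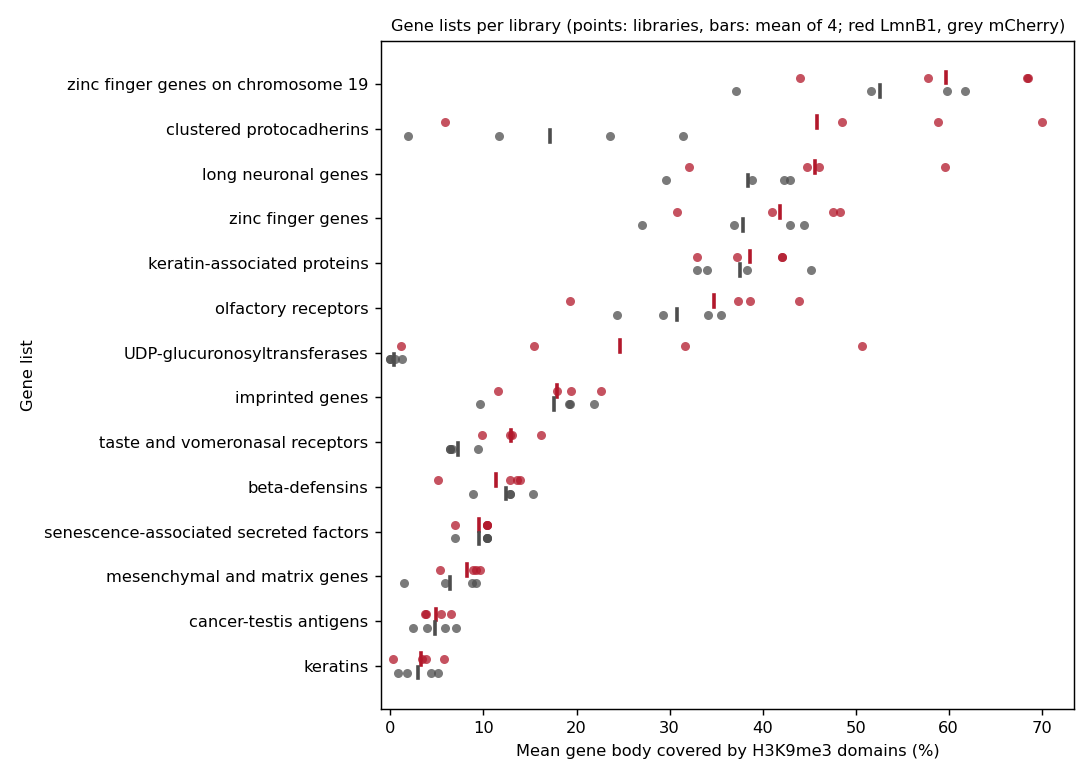
Mean percent of the gene body covered by H3K9me3 domains in each library (points) for the lists with the highest coverage, with bars for the mean of 4 libraries of a construct. Zinc finger genes on chromosome 19 are highest (59.7% and 52.6%), and LmnB1_6 replicate 2 lies at 5.91% for the protocadherins, far below the other LmnB1 libraries.

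By chromosome, coverage with LmnB1 and mCherry was 19.1 ± 2.54 and 14.03 ± 1.82 Mb on chromosome 13 and 20.4 ± 3.25 and 14.4 ± 2.07 Mb on chromosome 14 (SD, n = 4, exact permutation p = 0.0286 for both, adjusted 0.343). Each LmnB1 library lay above each mCherry library on both in Mb. As shares of covered length they were 3.695% and 3.16% on chromosome 13, with overlapping libraries (exact permutation p = 0.314), and 3.89% and 3.24% on chromosome 14 (exact permutation p = 0.0857). As a share of the library's covered length, chromosomes 1 (5.28% and 4.74%), 4 (4.51% and 3.84%) and 7 (6.17% and 5.59%) were higher with LmnB1 in all 4 libraries, and chromosome 18 was lower (3.23% and 4.54%), at an exact permutation p of 0.0286 and an adjusted p of 0.171. The share of chromosome 18 was 0.894% in LmnB1_6 replicate 2. Without that library the difference in its share was -0.539 points in place of -1.32 (exact permutation p = 0.0286, adjusted 0.229), and without any 1 mCherry library the exact permutation p was 0.143 or 0.171, settings chosen after seeing the data. Chromosome 18 held 24.8, 23.1, 23.4 and 3.19 Mb in the LmnB1 libraries and 15.5 to 23.3 Mb in the mCherry libraries. Chromosome X held 24.9 ± 14.5 Mb with LmnB1 and 32.5 ± 11.4 Mb with mCherry (exact permutation p = 0.514), with shares of 4.34% and 7.02% (exact permutation p = 0.0571, adjusted 0.274). Of the 24 chromosomes, 0 passed the adjusted threshold in the exact permutation test, with 2 at an unadjusted p below 0.05 in Mb and 4 as shares. The count in Mb was 1 without either mCherry_3 replicate or mCherry_4 replicate 1, 0 without mCherry_4 replicate 2 (smallest exact permutation p 0.0571), 8 without LmnB1_6 replicate 2, 5 at equal covered length and 1 in the highest-scoring 50% of each list. As shares it was 1 without mCherry_3 replicate 1 or mCherry_4 replicate 1, 0 without mCherry_3 replicate 2 (smallest exact permutation p 0.0571) and 2 without mCherry_4 replicate 2.

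Whether independent pairs of clones differed in the same bins depended on how they were paired. Across 2143 bins, which are not independent replicates, LmnB1_16 minus mCherry_3 correlated with LmnB1_6 minus mCherry_4 at r = 0.215 (rho = 0.224, jackknife SE 0.0551). LmnB1_16 minus mCherry_4 and LmnB1_6 minus mCherry_3 correlated at r = -0.202 (rho = -0.352, jackknife SE 0.0498). Differences within constructs gave r = 0.415 (rho = 0.537) for LmnB1_16 minus LmnB1_6 with mCherry_3 minus mCherry_4. With mCherry_4 minus mCherry_3 the same value changed sign (r = -0.415, rho = -0.537), the order of the clones being arbitrary. Their covariance is that of the first pairing minus that of the second, so they are no separate reference for either pairing. At equal covered length the second pairing turned to r = 0.0449.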

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

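In this part, both tests on LmnB1_6 replicate 2 were written before their results were seen. Among 116 groups of 4 libraries, 12 had a library far from the others of its construct by Dixon's test. Independent groups without ties would give about 5.8 by chance, but these groups overlap, and in 4 of the 12 the other 3 libraries had equal values, so that any different value in the remaining library stands apart. Single named genes were not tested this way, since their percent saturates.

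Chromosome 18 carried 3.19 Mb of H3K9me3 domains in LmnB1_6 replicate 2, against 23.1 to 24.8 Mb in the other LmnB1 libraries, and chromosome 16 carried 9.46 Mb against 19.9 to 21.1 Mb. The longest domain in that library was 1495 kb, against 3357 to 3429 kb in the others. Its beta-defensins were covered over 5.13%, against 12.8% to 13.9%, and its senescence-associated secreted factors over 6.90%, against 10.3%. In mCherry_4 replicate 2 the senescence-associated secreted factors were also covered over 6.90%, against 10.3% in the other mCherry libraries.

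LmnB1_6 replicate 2 also covered less of chromosome 10 (13.0 Mb) and X (6.80 Mb) than replicate 1 (36.6 and 29.8 Mb). Weaker enrichment under a fixed fold threshold was tested by raising the log2 threshold of replicate 1 to 0.90, where it covers as much as replicate 2, and this left 1.24 Mb on chromosome 18, 15.6 Mb on chromosome 10, 5.15 Mb on chromosome 16 and 0.657 Mb on X. The 1.24 Mb lay below the observed 3.19 Mb by more than the factor fixed in advance for a match, and the value that would have argued against this explanation was a longer remainder, so weaker enrichment may still be the source and cannot be told apart from others. A lower copy number of chromosome 18 could not be tested, because 0 strong domains matched there, against 60 on the other autosomes with a median log2 difference of -0.58. Both libraries come from the same clone and construct, so no biological explanation was tested.

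In mCherry_4 replicate 1 the depth relative to input was 0.421, against 0.816 to 0.859 in the other mCherry libraries, and taste and vomeronasal receptors were covered over 9.39%, against 6.45% to 6.64%. In mCherry_3 replicate 2 the longest domain was 3371 kb, against 2343 to 2479 kb, and HLA genes were covered over 3.59%, against 0 to 0.182%. In mCherry_3 replicate 1 the H3K9 methylation and HP1 machinery was covered over 0.0834% and epithelial junction genes over 0.228%, against 0 in the other mCherry libraries for both.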

How the results depend on the processing

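Leaving out both doubted libraries, using both gene ends and leaving libraries out of chromosome shares were chosen after seeing the data, and other alternatives were planned. Named genes, bins and lists count as reversed only when called in either setting. Of the comparisons, 181 values under an alternative stayed the same, 45 moved and 10 reversed. Values with a p stayed the same by direction and side of the threshold, counts within a fixed factor and correlations within their jackknife SE. No list or chromosome could pass with clone means (smallest exact permutation p 0.333) or a replicate block (0.0556). Those counts of 0 were fixed in advance, so the 181 are no measure of robustness. Of the named genes, regions, lists and chromosomes, 2485 values stayed, 33 passed the threshold newly and 24 no longer passed. Unpassed differences changed sign in 41 of 450 values of gene lists, 29 of 390 of chromosomes and 21 of 207 of chromosome shares. The cause was not tested for any value below, except that fewer domains enter the shortened lists. A domain is listed only past a fixed enrichment, so the weaker and shallower libraries limit what is called absent. The planned comparison at gene starts was not run.

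With domains counted in place of bases, the difference in overlap was 0.0444. With at least 80% in all 4 and 0 in the others there were 2 LmnB1 domains, with at least 1 bp 83 and 4 for LmnB1 and mCherry, and in at least 3 of 4 against at most 1 of 4 there were 966 and 17. In the highest-scoring 50% of each list there were 15 and 1 specific domains, 0 bins higher in limma (62 unadjusted), 1 gene lower and a correlation of -0.0569 for the second pairing of clones. With domains of at least 10 kb the difference in domain number was -1111, with 12 and 1 specific domains. At equal covered length the difference in domain number was -61.5, the overlap 0.0142, the mCherry-specific domains 3, the correlations 0.280 and 0.0449, and bins 0 higher and 1 lower in limma (69 unadjusted). With domains under 10 kb apart joined the overlap was 0.000334 and 12 bins were higher. Bins of 100 kb gave 57 higher and 3 lower and a correlation of 0.153 for the first pairing, and bins of 1 Mb gave 3 higher. Without a clone block 21 bins were higher, on the arcsine scale 3, and minus the library mean 15 with 1 lower. Without both doubted libraries there were 645 LmnB1 domains, 54 genes higher and 4 lower, and 2 bins higher. None of the 5 bins above passed then, though differences stayed as large (88.3 points on chromosome 8, 90.2 on chromosome 14 and 80 on chromosome 6, adjusted p in limma of 0.0509, 0.0661 and 0.649).

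Leaving out 1 library at a time gave a difference in covered length from 41.5 to 145.5 Mb, in domain number from 124 to 2110 and in median length from -13.1 to -3.42 kb, an overlap from -0.0421 (without mCherry_4 replicate 1) to 0.0456 (without LmnB1_16 replicate 2), 27 to 622 LmnB1 and 0 to 4 mCherry domains, 3 to 8 bins higher, and 5 to 55 genes higher and 2 to 8 lower. The extremes came without LmnB1_6 replicate 2 for 622 domains and 55 genes, and without mCherry_4 replicate 2 for 4 domains and 8 genes.

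The replicate numbers were not treated as pairing the libraries, since correlations of replicate differences between clones ran from -0.0568 to 0.245. Replicate 1 nevertheless had more domains and more covered length than replicate 2 in all 4 clones, by little in mCherry_3. With replicate number as a block, 8 bins were higher, 5 genes were higher and 2 lower, the smallest p of lists and chromosomes was 0.0556 in the exact permutation test, and no other call changed.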

Other observations

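The tests in this part were chosen only after the results were seen, but equal covered length, the fit without a clone block and leaving out mCherry_4 replicate 1 were planned settings. Some genes were covered by listed H3K9me3 domains in both replicates of 1 clone (at least 50% covered) and in none of the other 6 libraries (at most 10%). LmnB1_6 had 62 such genes. On chromosome 4 they included UGT2B11, UGT2B15 and UGT2B28 (100% in both replicates), UGT2B17 (89.8% and 100%) and UGT2B4 (100% and 91.3%), which conjugate steroids, with the saliva and casein genes STATH, HTN1, HTN3, ODAM and CSN3 (100% in both). Others were the endothelin receptor gene EDNRB and the potassium channel gene KCNJ3 (100% in both), the bitter receptor genes TAS2R16 and TAS2R38 (100% in both), ERBB4 (73.1% and 62.4%), CDH10 (100% and 76.0%), GPC5 (89.7% and 71.8%) and MAGEB18 (100% in both).

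LmnB1_16 had 18, among them the opioid precursor gene PENK, the transcription factor genes NOBOX and SALL3 and the olfactory receptors OR51L1 and OR52E2 (100% in both replicates), with SLCO1B3 (96.2% and 83.99%) and CDH4 (61.5% and 57.2%). mCherry_3 had 19, among them the water channel gene AQP4, EDN3 and CD209 (100% in both), SPRR2A (100% in both), SPRR2G (92.0% and 73.4%) and CYP2B6 (54.3% and 91.2%). mCherry_4 had 0, but 8 genes were outside the listed domains in that clone alone, among them RCVRN, KCNA5 and NKX1-1 (0 in both). Its replicate 1 had the lowest depth (0.421) and its replicate 2 the shortest list (320 Mb). Weaker detection in mCherry_4 thus cannot be told apart from a missing mark. In LmnB1_6 alone 4 genes were outside the listed domains, PDZRN3, OR2J2, MS4A3 and OR10G6 (0 in both). These are descriptions of single clones without a test, and UGT2B, SPRR2 and olfactory receptor genes are close copies whose reads were not told apart here.

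More domains and bins were specific to LmnB1 than to mCherry. Longer domain lists in the LmnB1 libraries are a candidate explanation. For domains, equal covered length left 21 LmnB1-specific and 3 mCherry-specific ones, so cutting the lists did not even out the counts. Regions are not replicates of a construct, and other splits of the libraries were not counted at that length, so this cannot decide on list length. For bins, equal covered length gave 0 higher and 1 lower in limma (69 unadjusted), so longer lists remain open there as well. The lamin B1 construct also remains open, with 2 clones for each construct. So does depth relative to input, which was higher in every LmnB1 library than in any mCherry library.

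With the clone as a block for bins and genes, as planned, and cut-offs without a model for domains, chance was not excluded for any of the 3 counts. Of the 35 splits of the libraries, 4 gave at least the 5 bins of the constructs, 6 at least the 7 genes and 5 at least the 25 domains. Of these, 2 of the 4 for bins and 4 of the 6 for genes break clones while the clone is a block, so they are no clean reference for chance. The highest counts of other splits were 300 bins, 38 genes and 122 domains, several times those of the constructs. The 38 genes came from LmnB1_16 with mCherry_3, a split that keeps clones whole. Without both doubted libraries that split called 36 genes, against 58 for the constructs. The 122 domains came from the split that joins the 4 longest lists, LmnB1_16, LmnB1_6 replicate 1 and mCherry_3 replicate 1 (529 to 646 Mb). It differs from the constructs by exchanging LmnB1_6 replicate 2, without which the constructs gave 622 LmnB1-specific domains. For domains the highest count thus went with list length. The 300 bins, and 254 in another split, came from splits that break clones while the clone is a block, and without the block those splits called 7 and 0. Without the block the constructs called 21 bins, more than any other split (1 of 35, highest other 16), and 10 genes (5 of 35, highest other 52), but such a fit treats replicates of a clone as independent.

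LmnB1_16 with mCherry_3 against LmnB1_6 with mCherry_4 called 38 genes, against 7 for the constructs. Without mCherry_4 replicate 1 the counts were 73 and 8, which argues against the depth of that library alone. At equal covered length they were 28 and 9, so cutting the lists did not remove the difference. The side of LmnB1_6 and mCherry_4 holds the shortest lists (357 Mb in LmnB1_6 replicate 2, 429 and 320 Mb in mCherry_4). It also holds the longest (646 Mb in LmnB1_6 replicate 1). Neither setting removes weaker enrichment in these libraries, so neither can decide on it. Without both doubted libraries the counts were 36 and 58, so this split no longer called more, but its own count had moved little and the count of the constructs had moved from 7 to 58. For bins this split called 8 with all libraries, 88 without mCherry_4 replicate 1, 3 at equal covered length and 0 in limma without both doubted libraries (87 unadjusted), against 5, 6, 1 and 2 for the constructs. The doubted libraries, weaker enrichment of single libraries and differences between clones remain open, and no group of the design separates these pairs.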
